A study of Mus musculus with 9 samples.

How the data were processed

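RNA was sequenced from Comma-1D cells, a mouse mammary epithelial line, sorted into 3 populations by Sca-1 and EpCAM: B (Sca-1 high, EpCAM low), L (Sca-1 low, EpCAM high) and bi (Sca-1 high, EpCAM high). Each population came in 3 arms, control, transduced with MYC and transduced with Her2, which gives 9 libraries, 1 for each population and arm. Per the labels, RNA was prepared with a ribosomal-RNA depletion kit (KAPA RNA HyperPrep with RiboErase, stranded), while the molecule label reads polyA RNA. Ribosomal-RNA loci took 9.7% to 16.1% of the reads in the files. The labels do not give the species of the transgenes, whether the arms were separate cultures, or a batch.

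The deposited files hold, per the file headers, an estimated (expected) read count per gene, a TPM value, and a gene length and effective length in bases. Per the submitters' processing notes they were made with Salmon 0.9.1 on mm10, and the transcript annotation release is not stated. The deposited lengths are weighted by transcript abundance and can be short (66.1 to 75.1 bases for Gapdh), so the deposited TPM of such genes depends on short isoforms. For this reason all main comparisons use the deposited estimated counts, and TPM serves as an alternative.

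The files list 54281 genes. Gene symbols were joined by Ensembl identifier, 53544 with the version and 563 without it, and 174 had no symbol. Coordinates and gene types came from the GENCODE annotation of the same genome build. Totals ran from 46.9 to 98.9 M reads: 54, 46.9 and 51.7 M for B control, MYC and Her2, 75.4, 69.3 and 75.6 M for L, and 98.9, 53.4 and 81.2 M for bi. A gene with 10 reads in the deepest library lies at 0.101 CPM.

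Counts were rounded to whole numbers, filtered with filterByExpr by arm (minimum count 10, minimum total 15), which kept 23834 genes, and scaled with TMM in edgeR 4.0.16 (R 4.3.3). Since no population and arm has a replicate, oncogene effects were tested as the average over the 3 populations with population as a block, and population differences as the average over the 3 arms with arm as a block, in an additive quasi-likelihood model on all 9 libraries with 4 residual degrees of freedom. The residual therefore holds the interaction of population and arm together with library noise. Should the 3 populations of an arm share a transduction, variation between transductions is not covered. Unless the controls carried a vector, an effect of transduction is not separated from that of the oncogene. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. Differences between single libraries within a population, and between the control libraries, have no test and are given as log2 ratios of TMM-scaled CPM with a prior count of 2.

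Gene lists for cell types, signalling and metabolism, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera on log2 CPM at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists of a comparison, and again with an estimated correlation and with fry (limma 3.58.1). No camera call held with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone. Within a population a list's median was set against 10000 random lists matched on expression. The rule names Myc, Erbb2, Ly6a and Epcam in every library, then for each comparison the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in all 3 blocks, a mean of at least 5 CPM in the higher group and a symbol other than those of predicted genes, clones and pseudogenes, or, where fewer than 5 pass, the 5 smallest p, and for each list described up to 2 members with the largest rise and up to 2 with the largest fall, or the member with the smallest p where none passed. For the values without a test, the 5 largest ratios each way at 10 CPM or more were named.

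A group or single library without reads was set to a floor of 3 reads, and folds against it are lower bounds. For 1 to 3 reads the ratio, here without a prior count, is given with its exact binomial 95% interval. Intervals and floors cover counting error alone. Setting list members with a group at 0 to their bound left the median of each list unchanged.

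The test was tried on simulated data with the same depth and size of groups and a spread estimated per gene from these libraries. In them 100 genes of at least 5 CPM were changed by each of 2 sizes. For an oncogene effect it found 38% of genes changed 2-fold and 99% of genes changed 4-fold, with 12 false among 149 calls. For a population effect it found 51% and 100%, with 12 false among 163 calls. Each simulated change was the same in every block, so these shares may be too high for the real data. In the real comparison of Her2 with control, genes with estimated changes above 4-fold missed the threshold.

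Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), effective-length offsets, no low-count filter, a filter of 50 reads in 3 libraries, thresholds of 0.01 and of a 2-fold change, a model on only the 6 libraries compared, a model without the block, and leaving out each library, population or arm. The fits on the TPM scales held only genes with a mean TPM of at least 1. A fit without ribosomal-RNA loci, small structural RNAs and virus-like genes was added after seeing the data. The virus-like family was also defined after seeing the data: transcripts matching Gm42427 or Gm43305 with blastn over at least 200 bases at 85% identity or more, covering at least 50% of the transcript. No library was left out of the main comparisons. No single-cell data were among the deposited files.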

Results

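Comma-1D is a mouse mammary epithelial cell line. The 9 libraries are 1 from each of 3 sorted populations, B (Sca-1 high, EpCAM low), L (Sca-1 low, EpCAM high) and bi (Sca-1 high, EpCAM high), in each of 3 arms (control, MYC, Her2). Every oncogene comparison is the average over the 3 populations and every population comparison the average over the 3 arms, with 3 libraries against 3. Gene values are log2 fold changes with their standard error (SE) and an adjusted p from edgeR, and levels are mean CPM, read counts scaled to library size.

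Myc was highest in the MYC library and Erbb2 in the Her2 library of every population, Ly6a was lowest in the L library of every arm, and Epcam in the B library. The labels do not give the species of the transgenes, so these counts may miss transgene reads or mix them with endogenous ones. Myc was at 285 CPM in the B MYC library, 207 in L MYC and 188 in bi MYC, against 114, 83.3 and 92.6 in the B, L and bi controls. Erbb2, which encodes Her2, was at 189 CPM in B Her2, 651 in L Her2 and 235 in bi Her2, against 53.3, 88.9 and 82.3 in the same controls. Among the controls Ly6a, which encodes Sca-1, was at 57.8 CPM in B, 6.53 in L and 18.4 in bi, and Epcam at 0.76 in B, 408 in L and 336 in bi. Ly6a also differed between the arms: it was at 112 CPM in B MYC, 12.8 in L MYC and 140 in bi MYC, against 19.5, 2.37 and 15.9 in the Her2 libraries of B, L and bi. Since Ly6a and Epcam defined the sort, their differences between populations are no finding.

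**Figure D1:**
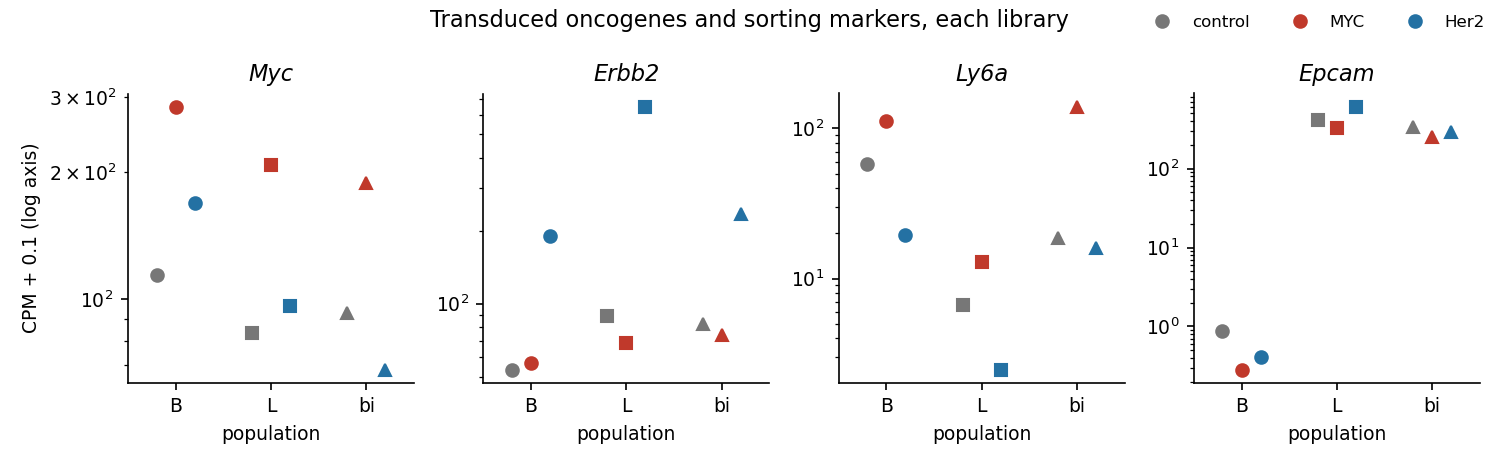
CPM plus 0.1 (log axis) of Myc, Erbb2, Ly6a and Epcam in each of the 9 libraries, 1 point per library, by population on the horizontal axis and by arm in colour. Myc is highest in the MYC library and Erbb2 in the Her2 library of every population, and Epcam lies below 1 CPM in the 3 B libraries alone.

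Population set the main axis of the data. The first principal component of the tested genes held 53.1% of the variance and put the 3 B libraries at -133 to -94.4, the bi libraries at 32.8 to 40.3 and the L libraries at 74.2 to 80.2. The next component, with 15.6%, put the 3 MYC libraries at -72.1 to -30.1 and the 3 Her2 libraries at 32.9 to 70.1. Population took 58.7% of the summed variance, arm 20.5% and the remainder 20.8%.

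**Figure D2:**
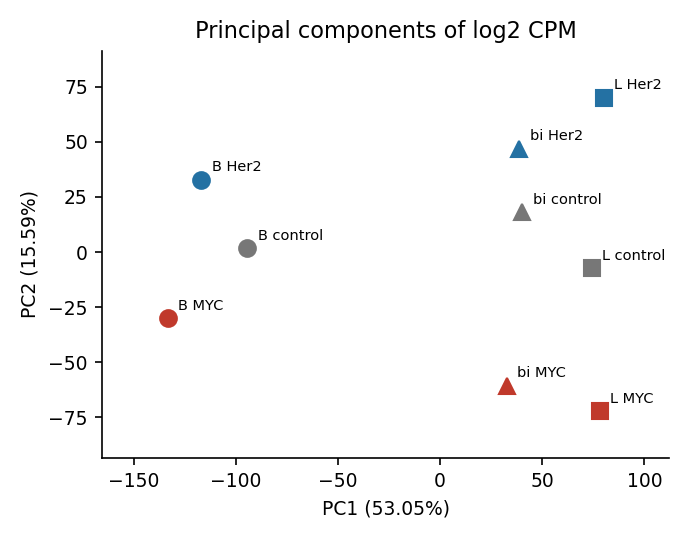
First and next principal components (arbitrary units, share of variance in brackets) of log2 CPM, 1 point per library, shape by population and colour by arm. The B libraries stand apart from L and bi on the horizontal axis, and MYC and Her2 libraries lie on opposite sides of 0 on the vertical axis.

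Most listed epithelial junction and luminal keratin genes were higher in L than in B, and most matrix and mesenchymal transition genes lower. Cdh1, which encodes E-cadherin, was at a mean of 481 CPM in L and 1.02 in B (log2 fold change 8.99, SE 0.61, adjusted p = 1.32e-05). The tight-junction gene Cldn4 (9.52) and the luminal keratin gene Krt7 (8.34) rose by similar amounts. In the other direction Thbs2, a matricellular protein gene, was at 38.6 CPM in L against 1110 in B (-4.72, adjusted p = 5.18e-05), and the chemokine gene Cxcl12 at 1.59 against 124 (-6.07, SE 0.34, adjusted p = 5.64e-06).

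In all, 4953 of 23834 tested genes differed between L and B, 2746 higher in L and 2207 lower. The strongest rises were in genes with no or almost no reads in B. Over the 3 libraries of each population, and against a floor of 3 reads for the group at 0, Krt79 was at least 920-fold higher in L, Armcx4 at least 597-fold, Zfp521 at least 588-fold, Kit at least 483-fold, Cwh43 at least 424-fold and Itprid1 at least 412-fold. The bound for Kit is mostly that of L MYC, which held 2059 of its 2133 reads in L, against 69 in L control. Kcnk1 had 2 reads in B, a ratio of 3750 (95% counting interval 1040 to 31000), Rps6ka6 2 reads and a ratio of 2450 (677 to 20200), Klk6 2 reads and 13300 (3690 to 110000), and Tmem54 1 read and 2690 (483 to 106000). The Klk6 ratio is mostly that of 1 library: of 39212 Klk6 reads in L, 37746 were in L Her2 and 909 in L control. Lower in L were the chemokine genes Ccl7 (-7.07), Ccl11 (-5.81) and Ccl8, the last with 1 read in L and a ratio of 1890 (338 to 74600) in favour of B, the complement gene C1s1 (-6.15, SE 0.35, adjusted p = 5.69e-06), the metalloelastase gene Mmp12 (-6.07), Ndufa4l2 (-5.88), Ccdc3 (-5.84), Ugt1a7c (-5.63) and Psg18 (-6.42). For Ccl8, Ccl11 and Psg18 the level in B was mostly that of B control. That library held 1172 of the 1283 Ccl8 reads in B. Ccl11 had 4710 reads in B control, 162 in B MYC and 15 in B Her2, and Psg18 had 934, 12 and 1.

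Of the epithelial junction and polarity list, 19 of 24 tested members rose in L and none fell (20 adjusted over the list alone), led by Ap1m2 (9.22) and Cdh1, with a median log2 fold change of 6.17 (camera adjusted p = 1.26e-15, adjusted p = 0.388 with an estimated correlation). Of the luminal keratins and shared luminal markers, 13 of 18 rose (13 adjusted over the list alone). Cldn4 and Krt7 came first, and the median was 3.63 (6.57e-08, adjusted p = 0.412 with an estimated correlation). The luminal progenitor list had 13 of 15 members up, among them Kit and Wfdc18 (8.91), and over the list alone 13 up and 2 down, with a median of 3.43 (1.09e-06, adjusted p = 0.431 with an estimated correlation). Genes of mitosis were higher in L as well: 37 of 52 members of the G2/M list rose (42 adjusted over the list alone), the largest being Psrc1 (2.01) and Ube2c (1.63), with a median of 0.87 (1.12e-10, adjusted p = 0.687 with an estimated correlation). Fatty acid synthesis had 7 of 16 members up (8 adjusted over the list alone), with Fasn at 2696 CPM against 600 (2.20, adjusted p = 0.000212), Scd2 at 1.69, and a median of 0.60 (0.00433, adjusted p = 0.475 with an estimated correlation).

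Fell in L: 13 of 24 mesenchymal transition members (15 adjusted over the list alone). Cdh11 (-5.21) and Tgfbi (-4.57) were the lowest, and the median was -1.18 (camera adjusted p = 6.57e-08, adjusted p = 0.388 with an estimated correlation). Fibroblast and matrix genes gave 12 of 19 fallen, the same number adjusted over the list alone, with Thbs2 and the collagen-binding proteoglycan gene Dcn (-4.38) in front and a median of -2.13 (5.54e-06, adjusted p = 0.2 with an estimated correlation). Antigen presentation had 10 of 17 lower (11 adjusted over the list alone), led by Nlrc5 (-2.79), the transactivator of class I genes, and the immunoproteasome gene Psmb8 (-2.39), with a median of -0.64 (5.49e-05, adjusted p = 0.2 with an estimated correlation). Without the MYC arm the count for L against B was 2946 genes, and it lay between 3308 and 5211 with any other library or arm left out. Of the 116 named genes that passed, 86 kept their call in every such fit.

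Like L, the bi population had more transcript of epithelial junction genes than B, and its mesenchymal transition list lay below B and above L. Against B, the splicing regulator gene Esrp1 rose by 8.58 on the log2 scale and the desmosomal cadherin gene Dsg3 by 7.21. Wfdc2, a secreted whey acidic protein family gene, was at 134 CPM in bi against 0.163 in B (log2 fold change 9.66, SE 0.49, adjusted p = 4.16e-06). Mmp13, a collagenase gene, was at 2.62 CPM in bi against 145 in B (-4.95, SE 1.01, adjusted p = 0.0112).

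Between bi and B 3094 genes differed, 1877 higher and 1217 lower in bi. With B at 0 reads, Krt79 was at least 852-fold and Ephb1 at least 420-fold higher in bi. Sostdc1, an inhibitor of BMP and Wnt signals, had 1 read in B and 14933 in bi, a ratio of 9810 (1760 to 387000). Ratios of 2250 (403 to 88700) for Tmem54, 2060 (569 to 17000) for Kcnk1, 1660 (460 to 13700) for Rps6ka6, 1030 (184 to 40600) for Tspan6 and 790 (218 to 6530) for Klk6 rest on 1 or 2 reads in B. Pof1b (9.69) was also higher. Besides Mmp13, the falls were in Ndufa4l2 (-4.73), Mmp12 (-4.57), the complement genes C1s1 (-4.02) and C1s2 (-3.82), Amigo2 (-3.72), Il13ra2 (-3.65), Nxph4 (-3.61), Myo7a (-3.61) and Enpp2 (-3.55).

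The junction and polarity list had 20 of 24 members up in bi (21 adjusted over the list alone). Esrp1 and Ap1m2 (8.54) came first, and the median was 4.30 (camera adjusted p = 4.89e-19, adjusted p = 0.346 with an estimated correlation). Luminal keratins and shared luminal markers had 11 of 18 up, also 11 adjusted over the list alone, with Cldn4 (7.21) and Cldn3 (6.05) and a median of 2.40 (8.75e-06, adjusted p = 0.476 with an estimated correlation). In the keratinocyte differentiation list 11 of 23 members rose (14 adjusted over the list alone). Dsg3 and S100a9 (7.20) came first, and the median was 2.02 (2.22e-06, adjusted p = 0.611 with an estimated correlation). Cholesterol synthesis gave 15 of 25 up (20 up and 2 down adjusted over the list alone). Hsd17b7 (1.51) and Pmvk (1.47) led, and the median was 1.003 (2.22e-06, adjusted p = 0.648 with an estimated correlation). G2/M genes gave 32 of 52 up (45 adjusted over the list alone). Psrc1 (1.55) and Ube2c (1.47) led, and the median was 0.86 (2.49e-13, adjusted p = 0.611 with an estimated correlation).

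Lower in bi than in B were 7 of 24 mesenchymal transition genes (11 adjusted over the list alone), with Cdh11 (-2.84), Tgfbi (-2.23) and a median of -0.72 (camera adjusted p = 1.89e-05, adjusted p = 0.439 with an estimated correlation). Antigen presentation had 7 of 17 down (1 up and 11 down adjusted over the list alone). Psmb8 (-2.12) and Nlrc5 (-1.95) led, and the median was -0.66 (6.03e-05, adjusted p = 0.346 with an estimated correlation), and hypoxia 7 of 18 down (1 up and 9 down adjusted over the list alone), with the prolyl hydroxylase gene Egln3 (-2.60) and the glucose transporter gene Slc2a1 (-1.66) and a median of -0.64 (0.000537, adjusted p = 0.648 with an estimated correlation). The count for bi against B was 1888 without the control arm, 1927 without the MYC arm, 1909 without B MYC, 1830 without bi control, 1963 without bi MYC and 2022 without bi Her2. Of the 93 named genes that passed, 56 kept their call in every fit with a library or arm left out.

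Bi and L differed in fewer genes, with the matrix and mesenchymal lists higher in bi and the luminal keratin list lower. Igfbp4, which binds insulin-like growth factors, was at 748 CPM in bi against 94.5 in L (log2 fold change 2.98, SE 0.31, adjusted p = 0.00814). Cxcl12 was at 16.1 against 1.59 CPM (3.30, SE 0.30, adjusted p = 0.00814). The casein gene Csn1s1 was at 0.227 CPM in bi against 12.7 in L (-5.41, SE 0.65, adjusted p = 0.0103), and the keratin genes Krt8 and Krt7 fell by 3.66 and 3.62 on the log2 scale.

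Here 179 genes passed, 118 higher and 61 lower in bi. Higher were also Mn1 (3.12), the monoacylglycerol lipase gene Mgll (3.05), Ccn4 (2.90), Ccl2 (2.89), Clmp (2.80), Ugt1a7c (2.78), Slit3 (2.66) and Sdk1 (2.66). Lower were Sftpd (-3.82), Hs3st1 (-3.10), the haptoglobin gene Hp (-3.04), Kit (-2.97), Exoc3l4 (-2.94), Ccrl2 (-2.89) and Pglyrp1 (-2.86). Of the 2133 Kit reads in L, 2059 were in L MYC.

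In the mesenchymal transition list 4 of 24 members rose in bi (9 adjusted over the list alone). The transcription factor gene Zeb1 (2.33) and Fstl1 (2.23) came first, and the median was 0.56 (camera adjusted p = 4.93e-08, adjusted p = 0.314 with an estimated correlation). Fibroblast and matrix genes had 3 of 19 up (7 adjusted over the list alone). Thbs2 (2.17) and Fbln2 (1.37) led, and the median was 1.08 (3.91e-08, adjusted p = 0.213 with an estimated correlation). The basal and myoepithelial list had Igfbp2 (2.30) up among 25 (9 adjusted over the list alone) and a median of 0.72 (9.03e-10, adjusted p = 0.314 with an estimated correlation). Against B the median of this list was 0.117 in bi and -0.521 in L, and it was called in neither comparison. Among luminal keratins and shared luminal markers Krt8, Krt7 and Cldn7 fell of 18 (9 adjusted over the list alone), with a median of -1.02 (2.47e-09, adjusted p = 0.314 with an estimated correlation). Luminal progenitor genes had 4 of 15 down (7 adjusted over the list alone). Csn3 (-3.79) and Kit were the lowest, and the median was -1.21 (7.75e-06, adjusted p = 0.399 with an estimated correlation). Of the junction and polarity list Marveld3 (-1.94) alone fell of 24 (1 up and 10 down adjusted over the list alone), with a median of -0.69 (2.62e-05, adjusted p = 0.568 with an estimated correlation). No interferon response gene of 32 passed over all genes (16 fell adjusted over the list alone). The list's median was -1.22 (5.85e-14, adjusted p = 0.401 with an estimated correlation), but -0.47 without L MYC and -0.57 without the MYC arm, and Gbp7, its member with the smallest p, had a log2 fold change of -1.25 at an adjusted p of 0.104.

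The count for bi against L was 106 without the MYC arm, 114 without the Her2 arm, 33 without L MYC, 47 without L Her2, 118 without bi control, 40 without bi MYC and 33 without bi Her2. The split ran from 32 higher and 1 lower without bi Her2 to 100 and 84 without B MYC. Of the 37 named genes that passed, Cxcl12, Mn1, Igfbp4, Slit3, Zeb1 and Fstl1 alone kept their call in every fit with a library or arm left out.

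**Figure D3:**
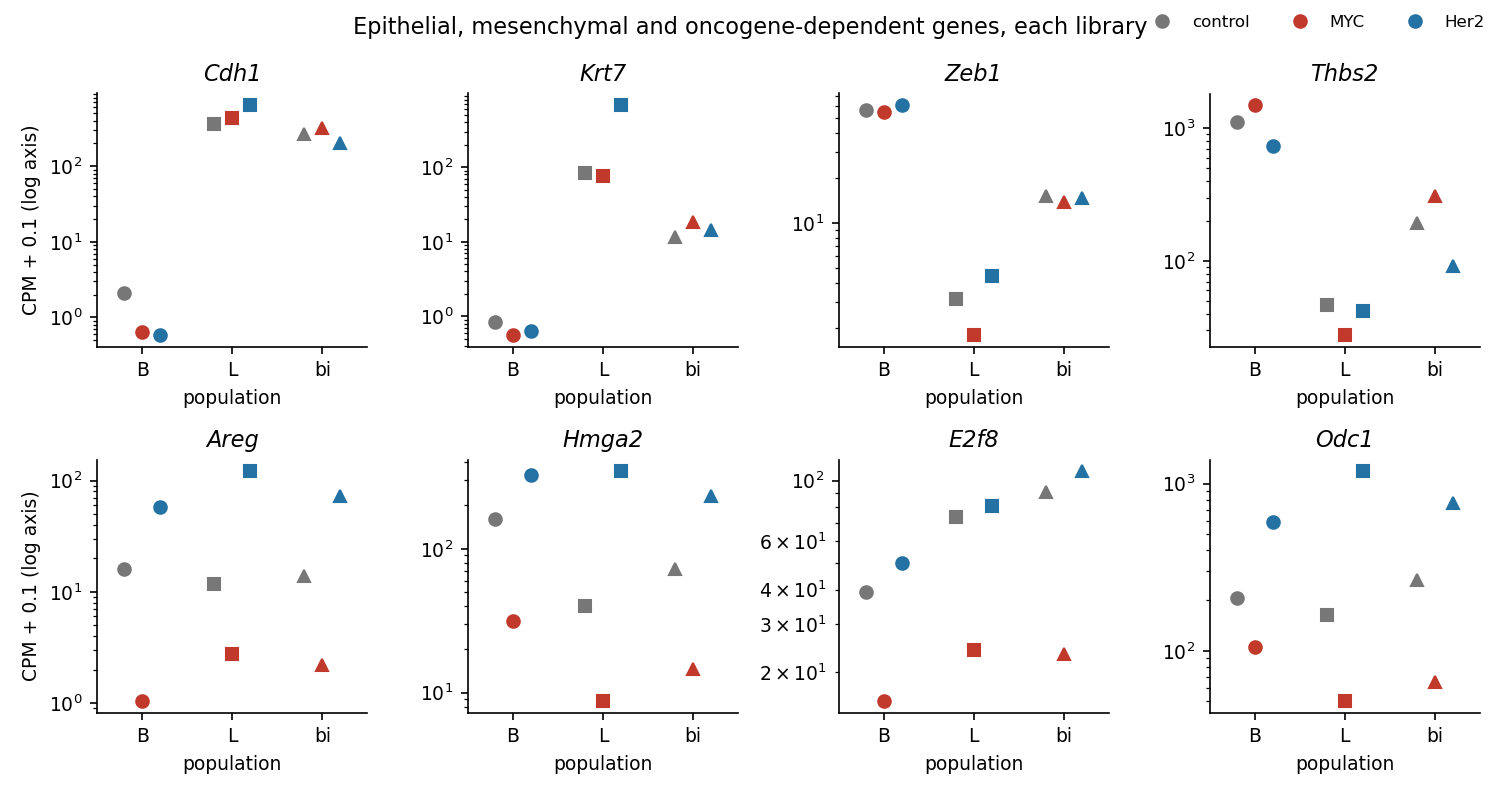
CPM plus 0.1 (log axis) of 8 genes named in the text, 1 point per library, by population on the horizontal axis and by arm in colour. Cdh1 and Krt7 are lowest in B, Zeb1 and Thbs2 lie in the order B, bi, L, and Areg, Hmga2, E2f8 and Odc1 are lowest in the MYC library of every population.

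The MYC libraries had less transcript of some G1/S genes and of the ligand genes Areg and Ereg than the controls. Areg, which encodes the EGF receptor ligand amphiregulin, was at a mean of 1.90 CPM with MYC against 13.8 in control (log2 fold change -2.97, SE 0.35, adjusted p = 0.0182), and Ereg, for the related ligand epiregulin, at 16.3 against 89.7 (-2.44, SE 0.36, adjusted p = 0.0329). The chromatin architecture gene Hmga2 was at 18.1 against 90.7 CPM (-2.31, adjusted p = 0.0395) and the osteopontin gene Spp1 at 204 against 802 (-1.98, adjusted p = 0.0283). Mxd4, whose product competes with MYC for its partner MAX, was at 96.7 against 33.7 CPM (1.66, SE 0.26, adjusted p = 0.0395), and Myc itself rose by 1.21 (SE 0.20, adjusted p = 0.0466).

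Over the 3 populations 87 genes differed, 24 higher and 63 lower with MYC, and 3317 had an unadjusted p under 0.05. The other rises were in Coq8a (2.61, SE 0.31, adjusted p = 0.0182), the pro-apoptotic gene Bmf (2.29), the acute-phase gene Saa3 (2.16), Tcp11l2 (1.93), the aldolase gene Aldoc (1.71), Miga1 (1.57), Slc25a23 (1.47), Gstm1 (1.38) and Vwa5a (1.36). The other falls were in U90926 (-4.42, SE 0.34, adjusted p = 0.000771), the connexin gene Gjb2 (-3.15), the neuronal tubulin gene Tubb3 (-2.80, SE 0.24, adjusted p = 0.00177), Il1rl1 (-2.55), Bmper (-1.89) and the nuclease and helicase gene Dna2 (-1.76). Each of these genes moved the same way in B, L and bi.

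Of the G1/S cell cycle list, 12 of 42 tested members fell with MYC and none rose (39 fell adjusted over the list alone). The replication-licensing gene Cdc6 (-1.75) and E2f8 (-1.64) were the lowest, and the median was -1.07 (camera adjusted p = 7.71e-33, adjusted p = 0.763 with an estimated correlation). In the G2/M list Ect2 (-1.20) fell of 52 (48 fell adjusted over the list alone), and the median was -0.84 (1.27e-28, adjusted p = 0.763 with an estimated correlation). The MYC target list had 2 of 61 members down and none up (1 up and 22 down adjusted over the list alone), with a median of -0.47 (9.52e-12, adjusted p = 0.763 with an estimated correlation), and its members that fell, Mcm5 (-1.31) and Mcm4 (-1.25), are subunits of the replicative helicase. By population the list's median log2 ratio was 0.01 in B, -0.60 in L and -0.69 in bi, each from 1 library against 1. The ERK output list had Ereg down of 23 (8 down adjusted over the list alone) and a median of -0.81 (1.94e-07, adjusted p = 0.763 with an estimated correlation). In the mesenchymal transition list Cdh11 (-3.99) fell of 24 (4 adjusted over the list alone), with a median of -0.33 (0.000741, adjusted p = 0.763 with an estimated correlation).

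No interferon response gene of 32 passed over all genes tested (10 rose adjusted over the list alone). The list's median was 1.14 (camera adjusted p = 4.1e-10, adjusted p = 0.763 with an estimated correlation), but 0.46 without the L population, and Mx2, its member with the smallest p, had a log2 fold change of 2.81 at an adjusted p of 0.0789. None of 17 FOXO targets passed (6 rose adjusted over the list alone), with a median of 0.41 (1.27e-05, adjusted p = 0.763 with an estimated correlation) and Pik3ip1 nearest to passing (1.19, adjusted p = 0.0735). Kit, the stem cell factor receptor gene and the only luminal progenitor gene of 15 that passed (3 adjusted over the list alone), rose by 4.49 (SE 0.46, adjusted p = 0.0224), but B had no Kit reads in either arm, so its change is that of L and bi.

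The count for MYC against control was 899 without the B population, 49 without L and 8 without bi, and, with single libraries left out, 500 without B Her2, 37 without L control, 15 without L MYC, 6 without bi control, 7 without bi MYC and 55 without bi Her2. With DESeq2 it was 966, without the population block 4, and of the 28 named genes that passed, only U90926 and Tubb3 kept their call in every fit with a library or population left out.

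The MYC libraries also held retrovirus-like transcripts at a level that the others lacked. Gm42427 has the reverse transcriptase motif YVDD in its longest open frame of 921 codons, Gm43305 lacks it, and neither was aligned to a virus sequence. Summed over the 9 tested genes of a family found by sequence similarity, they came to 10720 CPM in B MYC, 15994 in L MYC and 12110 in bi MYC, against 396, 303.0 and 563 in the B, L and bi controls and 286, 224 and 643 in the Her2 libraries. The MYC libraries were thus 27.1, 52.8 and 21.5 times their controls in B, L and bi. Gm42427 carried most of it (8886 against 176 CPM, log2 fold change 5.69, SE 0.33, adjusted p = 0.000165), with Gm43305 (4.67, adjusted p = 0.0114) and Gm48275 (7.01, adjusted p = 0.00048). The family and these genes were chosen after their values were seen.

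**Figure D4:**
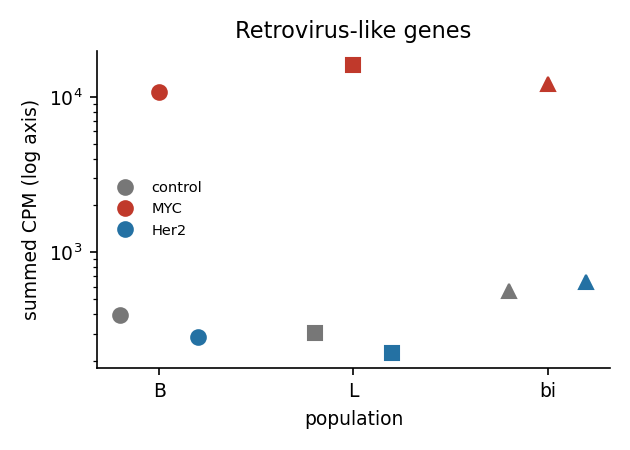
CPM (log axis) summed over the 9 retrovirus-like genes tested, 1 point per library, by population on the horizontal axis and by arm in colour. The 3 MYC libraries lie at 10720 or above, the 6 others at 643 or below.

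Few genes passed for Her2 against control. Thsd4, for an extracellular matrix protein, was at 17.6 CPM with Her2 against 4.63 in control (log2 fold change 2.03, SE 0.21, adjusted p = 0.0485). The epithelial transcription factor gene Ehf was at 67.4 against 184 CPM (-1.53, SE 0.17, adjusted p = 0.0485), and the phosphate transporter gene Slc34a2 at 0.914 against 9.97 (-3.53, SE 0.41, adjusted p = 0.0485). Erbb2 did not pass in this comparison, with a log2 fold change of 2.12 (SE 0.31, adjusted p = 0.0573), although it was higher in the Her2 library of each of the 3 populations.

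In all 5 genes passed, 3 higher and 2 lower, and 2097 had an unadjusted p under 0.05. The 2 not yet named, Crisp1 and Lilr4b, were higher with Her2 but lay outside the rule for named genes and are given because the count is small, after their values were seen. Next by p among the higher genes, none of them passing, came Areg (log2 fold change 2.497, adjusted p = 0.0549), the interleukin gene Il1a (1.46, adjusted p = 0.0573) and the sodium-proton exchanger gene Slc9a2 (4.10, adjusted p = 0.0573). On the lower side, also not passing, stood Hp (-4.72), Rassf4 (-2.02) and the netrin gene Ntn4 (-1.22), each at an adjusted p of 0.0549.

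No member of the ERK output list passed among 23 over all genes, but 10 rose adjusted over the list alone, and the median was 0.71 (camera adjusted p = 1.87e-09, adjusted p = 0.605 with an estimated correlation). Its member nearest to passing was the cytokine gene Il11 (2.20, adjusted p = 0.129). The fibroblast and matrix list had none of 19 past the test over all genes and 2 up and 9 down adjusted over the list alone, with a median of -0.82 (0.000218, adjusted p = 0.333 with an estimated correlation) and Col3a1 at -3.76 (adjusted p = 0.0549). In the G2/M list no gene of 52 passed over all genes, nor adjusted over the list alone, with a median of -0.37 (5.12e-10, adjusted p = 0.766 with an estimated correlation) and Kif11 nearest to passing (-0.60, adjusted p = 0.297). The count for Her2 against control was 0 without the B population, 2 without L and 132 without bi, and, with single libraries left out, 0 without B control, 32 without B MYC, 10 without B Her2, 2 without L control, 48 without L MYC, 0 without L Her2, 25 without bi control, 17 without bi MYC and 91 without bi Her2. DESeq2 called 509 genes and limma-voom 0, and none of the 3 named genes that passed kept its call in every such fit.

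Set against each other, the ERK output and G1/S lists were lower with MYC than with Her2 and the interferon list higher. Areg was at 1.90 CPM with MYC and 84.2 with Her2 (log2 fold change -5.46, SE 0.38, adjusted p = 0.000288), Hmga2 at 18.1 and 302 (-4.32, SE 0.40, adjusted p = 0.00202), and the ornithine decarboxylase gene Odc1 at 73.1 and 848 (-3.57, SE 0.39, adjusted p = 0.00381). Hp was at 89.6 CPM with MYC and 0.34 with Her2 (7.40, SE 0.68, adjusted p = 0.00191), and Postn, for the matrix protein periostin, at 322 and 7.64 (6.33, SE 1.46, adjusted p = 0.0415). Erbb2 was lower with MYC (-2.24, adjusted p = 0.00687) and Myc higher (1.09, adjusted p = 0.0205).

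Here 1089 genes differed, 581 higher and 508 lower with MYC. Higher with MYC were also Wfdc12 (6.61), Serpina3n (5.49), the Wnt inhibitor gene Wif1 (4.19), Sftpd (3.99), the oxytocin receptor gene Oxtr (3.97), Wfdc18 (3.97), Slc34a2 (3.95) and Steap4 (3.85). Higher with Her2 were Wnt7a (-6.85, SE 0.71, adjusted p = 0.00328), the stromelysin gene Mmp10 (-6.77), Il24 (-6.57), Sema7a (-6.16), the natriuretic peptide gene Nppb (-4.92), Dynap (-4.74), Fer1l6 (-4.70) and Parvb (-4.12).

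In the ERK output list 14 of 23 members were lower with MYC and none higher (19 lower adjusted over the list alone). The feedback inhibitor gene Spry4 (-3.74) and Il11 (-3.51) were the lowest, and the median was -1.43 (camera adjusted p = 2.27e-15, adjusted p = 0.609 with an estimated correlation). Of the ERBB receptors and ligands, 1 of 15 was higher with MYC and 5 lower (2 and 6 adjusted over the list alone), with the receptor gene Egfr (1.10) up, the ligand genes Areg and Ereg (-3.22) down and a median of -0.83 (0.00331, adjusted p = 0.609 with an estimated correlation). G1/S genes had 23 of 42 lower with MYC (38 adjusted over the list alone). E2f8 (-1.88) and Cdc6 (-1.64) led, and the median was -0.85 (2.7e-21, adjusted p = 0.609 with an estimated correlation). MYC targets had 1 of 61 higher with MYC, Sord (1.39), and 4 lower (1 and 8 adjusted over the list alone). Odc1 and Mcm4 (-1.07) were the lowest, and the median was -0.33 (1.71e-07, adjusted p = 0.73 with an estimated correlation). Mesenchymal transition genes had 4 of 24 lower with MYC (6 adjusted over the list alone). Cdh2 (-2.55) and Cdh11 (-2.46) led, and the median was -0.50 (0.0015, adjusted p = 0.609 with an estimated correlation).

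Interferon response genes had 10 of 32 higher with MYC (27 adjusted over the list alone). The antiviral genes Mx2 (3.24) and Ifit1 (2.78) came first, and the median was 1.56 (camera adjusted p = 2.45e-12, adjusted p = 0.609 with an estimated correlation). It was 0.75 without L MYC and 0.89 without the L population. FOXO targets had 5 of 17 higher (8 adjusted over the list alone). The ubiquitin ligase gene Fbxo32 (2.52) and Pik3ip1 (1.73) led, and the median was 0.45 (0.00177, adjusted p = 0.609 with an estimated correlation). Luminal progenitor genes had 7 of 15 higher and 1 lower (7 and 1 adjusted over the list alone), with Kit (7.78, a change of L and bi alone, since B had no Kit reads) and Wfdc18 up, Itga2 (-2.71) down and a median of 1.40 (0.00359, 0.058 without L MYC, and adjusted p = 0.661 with an estimated correlation). The inflammatory and NF-kB list split, 6 of 28 higher with MYC and 5 lower (9 and 9 adjusted over the list alone), with the chemokine gene Ccl7 (3.32) and Saa3 (3.04) up, the prostaglandin synthase gene Ptgs2 (-3.64) and Csf2 down, the last with 2 reads over the MYC libraries and a ratio of 235 (64.7 to 1940) in favour of Her2. Its median of 0.15 and mean of -0.25 differ in sign, and the list was not called (camera adjusted p = 0.999).

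The count for MYC against Her2 was 2081 without the B population, 320 without L and 462 without bi, and, with single libraries left out, 394 without L MYC, 289 without L Her2, 219 without bi MYC and 615 without bi Her2. Without the population block it was 6, and of the 76 named genes that passed, 24 kept their call in every fit with a library or population left out. More genes were lower than higher without the B population (864 higher and 1217 lower), bi (208 and 254), L Her2 (123 and 166) or bi Her2 (250 and 365). In every other such fit more were higher.

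The same controls serve MYC and Her2. Across 10753 genes the log2 fold changes of MYC and Her2 against control correlated at r = 0.038, with a covariance of 0.008. Libraries simulated without an arm effect, the controls redrawn with them, gave a mean r of 0.5 over 20 simulations. The simulated covariance was 0.039, a difference of -0.031. No gene passed in both comparisons. At an unadjusted p under 0.05, 249 genes moved the same way in both (112 simulated, 130 for independent lists) and 152 opposite ways (1.5 simulated, 119 for independent lists). Since the simulated lists hold no arm effect, their counts are no baseline for the overlap of the real lists. The controls are too few to split, so part of the excess in the same direction over independent lists may come from them, and genes are not independent replicates.

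Within each population 1 library stands against 1, so the following are values without a test, counted at a log2 ratio of at least 1 either way and at least 5 CPM in 1 of the libraries. With MYC 730 genes differed from control in B (389 higher, 341 lower), 703 in L (322 and 381) and 1144 in bi (530 and 614). With Her2 1030 differed in B (501 and 529), 949 in L (642 and 307) and 387 in bi (145 and 242). In B with MYC, the decorin gene Dcn was 20-fold higher, Il13ra2 19-fold, the keratin gene Krt15 17.4-fold, Cdsn 10.2-fold and Arhgap20 7.15-fold. Mill1 was 241-fold lower there, Psg18 54.7-fold, Mmp12 25.3-fold, Ccl11 22.4-fold and Gjb2 20.8-fold. In L with MYC, Kit was 28.2-fold higher, the imprinted RNA gene H19 24.4-fold, Atp6v1b1 23.9-fold, Alpl 18.2-fold and Hp 17.6-fold. U90926 was 26.4-fold lower, Prl2c2 11.4-fold, Krt90 10.6-fold, Padi1 8.23-fold and Krt79 5.52-fold. In bi with MYC, Krt15 was 59.3-fold higher, Wfdc12 50.8-fold, Ndufa4l2 33.4-fold, Chil1 13.3-fold and Prelp 12.8-fold. U90926 was 20.2-fold lower, the smooth muscle genes Tagln and Acta2 9.55-fold and 8.09-fold, Adam12 9.04-fold and Gjb2 7.7-fold.

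In B with Her2, the carbonic anhydrase gene Car6 was 195-fold higher, Cdsn 54.2-fold, Itgb7 40.2-fold, Avil 35.4-fold and Trib3 26.7-fold. Ccl11 was 264-fold lower, Postn 149-fold and Ccl8 80.3-fold. Mill1 and Psg18 had 1 read each in B Her2, for ratios of 2100 (376 to 82800) and 865 (155 to 34200) in favour of control. In L with Her2, Fer1l6 was 63.6-fold higher, Parvb 61.5-fold, Gpr149 59.1-fold, Sema7a 47.5-fold and Klk6 46.7-fold. Postn was 42.3-fold lower, Hp 16.9-fold, Slc34a2 10.9-fold, Steap4 9.93-fold and Adamts15 7.88-fold. In bi with Her2, the glutamate receptor gene Grik3 was 25.2-fold higher, Mmp10 11-fold, Mir6236 9.38-fold, Il24 7.94-fold and Gsta1 7.26-fold. The prolactin receptor gene Prlr was 6.55-fold lower, Rassf4 5.57-fold, Col5a2 4.32-fold, Steap4 4.18-fold and Lcn2 3.96-fold.

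Log2 ratios to control correlated across genes at r = 0.748 between L and bi, 0.462 between B and bi and 0.354 between B and L for MYC. For Her2 the values were 0.542, 0.099 and 0.287. These are across 10753 genes within pairs of libraries, and genes are not independent replicates. With MYC the interferon list's median log2 ratio was 2.06 in L, 0.83 in bi and 0.23 in B, and the G1/S median -1.02, -1.45 and -0.66. With Her2 the ERK output median was 1.10 in L, 0.68 in bi and 0.46 in B, and the fibroblast and matrix median -0.21, -0.55 and -1.57. Whether the populations differ in these medians was not tested.

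**Figure D5:**
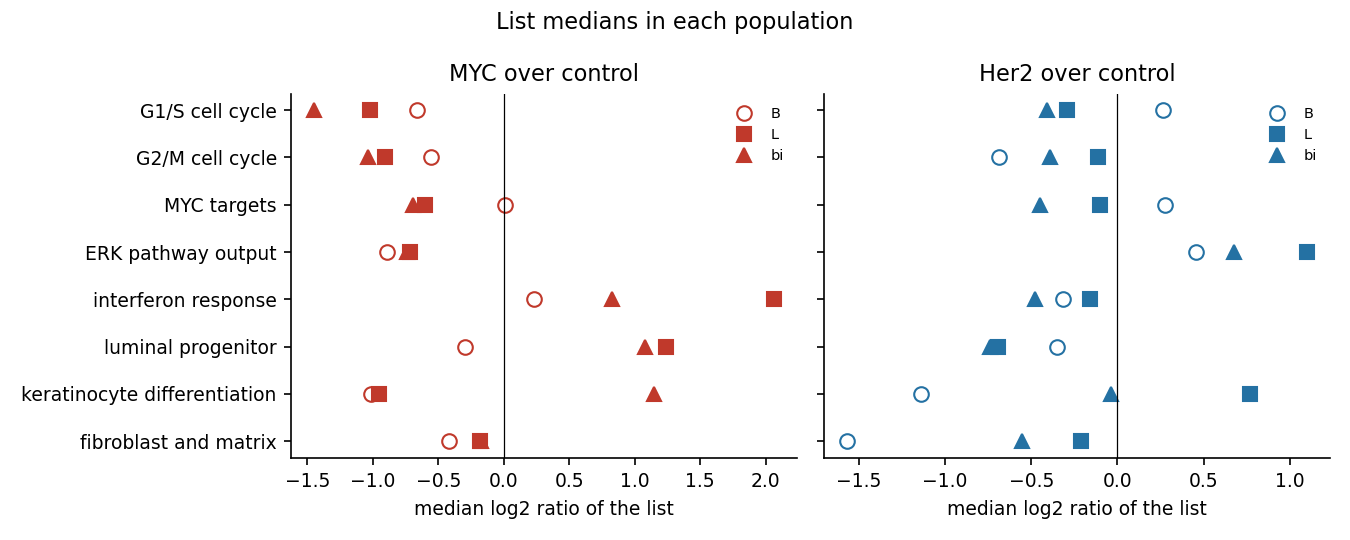
Median log2 ratio of 8 lists, MYC (left) and Her2 (right) over control, 1 point per population. With MYC the G1/S median lies below 0 and the interferon median above 0 in all 3 populations, from -0.66 in B to -1.45 in bi for G1/S and from 0.23 in B to 2.06 in L for interferon. The points carry no error, since each rests on 1 library against 1.

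Among the controls alone, 1933 genes differed between L and B (1032 higher in L, 901 lower), 1615 between bi and B (984 and 631) and 330 between bi and L (193 and 137). Esrp1 was 1310-fold higher in L and 1020-fold higher in bi than in B. With B control at 0 reads, Krt79 was at least 554-fold and Sostdc1 at least 380-fold higher in L, and at least 470-fold and 803-fold higher in bi. Kcnk1 and Rps6ka6 had 1 read each in B control, for ratios of 2720 (488 to 107000) and 2300 (412 to 90700) in L and of 1920 (344 to 75700) and 1700 (305 to 67100) in bi. Mmp12 was 531-fold lower in L than in B and 195-fold lower in bi, and Ccl11 524-fold and 197-fold. Psg18 had 3 reads in either population, ratios of 425 (145 to 2070) over L and 518 (177 to 2520) over bi in favour of B. Ccl8 had 1 read in L, a ratio of 1600 (287 to 63300), and was 223-fold lower in bi. Ccl7 was 195-fold lower in L and Ndufa4l2 154-fold lower in bi. Between bi and L, the smooth muscle actin gene Acta2 was 16.3-fold higher in bi, Mn1 13.4-fold, Adam12 11.6-fold, Cxcl12 11-fold and the stem-cell-associated receptor gene Lgr6 7.41-fold. The lactoferrin gene Ltf was 10.7-fold lower, Krt7 7.26-fold, Chil1 6.17-fold, the lipocalin gene Lcn2 5.96-fold and Hp 5.35-fold.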

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

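All values in this part were picked after the libraries had been seen, including the minimum size of 0.5 for a list's median, and none of the differences between populations was tested. The keratinocyte differentiation list, which holds genes of the cornified envelope and desmosomes, moved in opposite directions in different populations. With MYC its median log2 ratio to control was 1.14 in bi and -1.01 in B, a difference of 2.16, and -0.95 in L. With Her2 it was 0.77 in L and -1.14 in B, a difference of 1.91, and -0.04 in bi. In all, 20 of 76 pairs of an arm and a list had medians of opposite sign outside the central 95% of matched random lists in different populations, and these were the pairs with at least 0.5 on both sides. Each rests on 1 library against 1, so that a population's own response and a difference between single libraries are not separated.

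The deposited effective length of Erbb2, which the main comparisons of counts do not use, was higher in the Her2 libraries (1918 to 2037 bases) than in the controls (1619 to 1639), the lowest Her2 library being 1.17 times the highest control. This is a signal in a column outside the main measurement, and the transcripts behind it are not in the files.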

How the results depend on the processing

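Among the 6 tested counts, each setting below moved the count by more than 1.5 times, and the cause was not tested unless the setting states it. At an adjusted p under 0.01, by construction, there were 6 genes for MYC against control, 0 for Her2 against control, 186 for MYC against Her2, 2618 for L against B, 1339 for bi against B and 19 for bi against L. For MYC against control (87) RLE gave 54, upper-quartile scaling 222, DESeq2 966, log2(TPM + 1) 872, log2(TPM + 0.1) 868, no low-count filter 944, the filter of 50 reads 242, only the 6 libraries compared 695 and no population block 4. For Her2 against control (5) RLE gave 32, DESeq2 509, no low-count filter 619, only the 6 libraries compared 221 and the added fit without structural RNA and virus-like genes 3, while upper-quartile scaling, limma-voom, both TPM scales, effective-length offsets, the filter of 50 reads and no population block each gave 0. For MYC against Her2 (1089) DESeq2 gave 1887, log2(TPM + 1) 673, no low-count filter 2089 and no population block 6. For bi against B (3094) no arm block gave 1430. For bi against L (179) DESeq2 gave 663, log2(TPM + 1) 8, log2(TPM + 0.1) 12, no low-count filter 698, the filter of 50 reads 103 and no arm block 20. With 1 library, population or arm left out, where a lone library is assumed to vary like the other groups, the counts ran from 6 to 899 for MYC against control, 0 to 132 for Her2 against control, 219 to 2081 for MYC against Her2, 2946 to 5211 for L against B, 1830 to 3275 for bi against B and 33 to 234 for bi against L. Of the values without a test, log2(TPM + 1) gave 226 genes in place of 387 for Her2 in bi and 183 in place of 330 for bi against L among the controls.

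Some settings also shifted the balance of higher and lower genes. The TPM fits of the tested comparisons held only genes with a mean TPM of at least 1, so scale and gene set are not separated there. On the TPM scales the median log2 fold change of all genes stood at -0.16 and -0.19 for MYC against control (0.03 in the main test) and at -0.11 and -0.14 for Her2 against control (-0.01), and the split for MYC against control was 50 higher and 822 lower, then 43 and 825 (24 and 63 in the main test). It was 364 and 602 with DESeq2, 4 and 0 without the block and 4 and 2 at an adjusted p under 0.01. For Her2 against control it was 24 and 8 with RLE, 250 and 259 with DESeq2, 101 and 120 with only the 6 libraries compared and 1 and 2 in the added fit (3 and 2). For MYC against Her2 the TPM scales gave 181 and 492, then 188 and 539, upper-quartile scaling 645 and 671, no low-count filter 960 and 1129, the added fit 540 and 653 and no block 4 and 2 (581 and 508). For L against B the TPM scales gave 1589 and 1948, then 1624 and 1936 (2746 and 2207). For bi against B they gave 1094 and 1224, then 1168 and 1164, no block gave 1011 and 419 and an adjusted p under 0.01 gave 950 and 389 (1877 and 1217). For bi against L DESeq2 gave 349 and 314, no low-count filter 354 and 344, only the 6 libraries compared 132 and 135, log2(TPM + 0.1) 11 and 1, no block 18 and 2 and an adjusted p under 0.01 19 and 0 (118 and 61). Within populations log2(TPM + 1) gave 69 and 559 for MYC in B (389 and 341), 231 and 549 for Her2 in B (501 and 529), 320 and 353 for Her2 in L (642 and 307), 239 and 686 for MYC in bi (530 and 614), 123 and 103 for Her2 in bi (145 and 242), 734 and 872 for L against B among the controls (1032 and 901), and 538 and 662 for bi against B among the controls (984 and 631), and RLE gave 568 and 500 for Her2 in B.

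Of the named genes that passed, 0 changed direction under any setting. Of 353 such calls DESeq2 kept 349, RLE 348, limma-voom 338, upper-quartile scaling 332, effective-length offsets 331, only the 6 libraries compared 335 and no block 153. Of the 318 that could be tested on the TPM scales log2(TPM + 1) kept 222 and log2(TPM + 0.1) 235, and the filter of 50 reads kept 306 of 327. In all 179 calls ended with at least 1 library, population or arm left out. All 92 called lists lost their call with an estimated correlation, 22 kept it with fry and 90 with RLE, and 46 lost it with at least 1 library, population or arm left out. The direction of a called list turned in 6 leave-outs, each of which also ended the call. They are cholesterol synthesis for Her2 against control without the B population (adjusted p = 0.437) and without B Her2 (0.64), with a range over all leave-outs from 8.9e-06 to 0.64, G1/S for Her2 against control without bi control (0.665, range 3.12e-08 to 0.957), hypoxia for Her2 against control without L Her2 (0.961, range 0.00207 to 0.961), and the proteasome list for MYC against control without L MYC (0.912, range 1.97e-06 to 0.975) and for MYC against Her2 without the L population (0.953, range 0.000125 to 0.953). Of the 136 list tests that were not called, 73 were called in the same direction and 10 in the opposite one in at least 1 alternative. The labels give no replicate numbers shared between groups, and the pairing in the main test is that of the design, with the population or the arm as block. The filter's minimum count of 10 reads holds at the median library size, so a shallower library meets it with fewer reads and a deeper one needs more. Genes at 0 reads in a population are bounds, not absences.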

Other observations

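Signalling components also differed between the populations. L had more of the receptor adaptor gene Grb7 than B (log2 fold change 9.07), and of Erbb4 (at least 15.2-fold), but less of the ligand gene Epgn (-2.27) and of Egfr (-0.73), and the list of ERBB receptors and ligands as a whole had 3 of 15 members up and 2 down (3 and 3 adjusted over the list alone) and was not called (camera adjusted p = 0.668). In bi against B, 5 of 15 Wnt targets rose and none fell (7 adjusted over the list alone), with the Wnt inhibitor genes Wif1 (7.95) and Nkd2 (7.85) first and a median of 0.70 (camera adjusted p = 0.00894, adjusted p = 0.346 with an estimated correlation). Adipocyte genes had 3 of 11 up in L against B (4 adjusted over the list alone), with Cidea (4.34) and the lipoprotein lipase gene Lpl (2.55) and a median of 0.58 (0.00562, adjusted p = 0.475 with an estimated correlation). Of the stem cell associated list, Bcl11b (1.88) and Ly6e (1.24) were higher in bi than in L among 15 (2 up and 1 down adjusted over the list alone), with a median of 0.31 (0.0425, adjusted p = 0.568 with an estimated correlation), a call that ended without L control (adjusted p = 0.278), bi Her2 (0.123), bi MYC (0.0685), L MYC (0.0569), B control (0.0699), B MYC (0.0592), the control arm (0.168) or the MYC arm (0.0711).

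Between the oncogenes, fibroblast and matrix genes had 5 of 19 members higher with MYC than with Her2 and none lower (8 and 1 adjusted over the list alone), with Postn (6.33) and the collagen gene Col3a1 (2.73) first and a median of 0.39 (camera adjusted p = 0.0322, adjusted p = 0.609 with an estimated correlation), a call that ended without the B population (0.384), B Her2 (0.387), B MYC (0.089) or B control (0.0715). Antigen presentation had 4 of 17 higher with MYC (6 adjusted over the list alone), with the immunoproteasome genes Psmb9 (2.48) and Psmb8 (1.89), a median of 0.20 (0.0221, adjusted p = 0.609 with an estimated correlation) and a fry adjusted p of 0.00137, and its camera call ended without the B population (0.15), B MYC (0.0815), B Her2 (0.0767) or bi Her2 (0.0678). Reads on histone genes, whose messages lack a poly(A) tail, made up 0.52%, 0.82% and 0.97% of the control libraries of B, L and bi, 0.25%, 0.50% and 0.38% of the MYC libraries and 0.15%, 0.59% and 0.75% of the Her2 libraries.

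Of the tests that follow, the one of a single contaminated or mislabelled library and the sums with genes chosen in the other arms were chosen after the values were seen, and the patterns themselves were found in these data. The 6 MYC and control libraries can be split 3 against 3 in only 10 ways, as can those of every other comparison, too few for a share under 0.05, and 1 of the 10, the real grouping, gave as many genes in each comparison. The real value and the highest of the other splits were 87 and 3 for MYC against control, 5 and 0 for Her2 against control, 1089 and 0 for MYC against Her2, 4953 and 0 for L against B, 3094 and 0 for bi against B, and 179 and 7 for bi against L. In the other splits part of any real difference goes into the residual, which lowers their counts, so the gap to the real value decides nothing.

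Summed over the family, the retrovirus-like transcripts were higher in all 3 MYC libraries, although 6 of the 9 genes had a negative log2 fold change. Reads moved between near-identical copies within the family would leave its sum in place, but the lowest of the 3 ratios of summed CPM was 21.5. Moves from copies outside the family are not covered. The sum rests mostly on Gm42427 (8886 CPM with MYC) and Gm43305 (3381 CPM), picked for their rise. A single contaminated library would leave the others near control, but the lowest MYC library was 16.7 times the highest of the 6 others. Whether the MYC cells carry a virus or packaging construct is left open: the difference of 3.43 between the median log2 fold changes of genes over 97% and under 93% identical to the queries decides nothing, since the former include the queries Gm42427 and Gm43305, picked for their rise (0.59 without them), and of the 6 genes over 97% identical Gm42428 (-0.07, adjusted p = 0.976) and Gm46223 (-8.95, adjusted p = 0.0599) did not pass and AC158975.2 fell by 1.02. A response of the cells' own proviruses to MYC is a biological explanation that was not tested, and the interferon medians of the same libraries (1.14 over the 3 populations, 0.46 to 1.59 with a library or population left out) were not tested for a link. Outside the family as defined, Gm48274 (log2 fold change 7.62, adjusted p = 0.000145) and Gm42031 (6.54, adjusted p = 0.000324) rose as well, both named after their values were seen. Gm48274 did not meet the family's rule for a match but lies between the family members Gm46223 and Gm48275 on chromosome 10.

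The cell-cycle lists had medians below 0 with MYC, with 12 of 42 G1/S and 1 of 52 G2/M members past the test over all genes, and neither was called with an estimated correlation (adjusted p = 0.763) or with fry (0.058 and 0.123). Scaling or library composition would bring the G1/S median toward 0 under some other scaling, but the highest of 8 others was -1.02 and the lowest -1.22. Since all 8 kept the median of all genes between -0.188 and 0.052, they could hardly do so. They show that G1/S genes were lower relative to other genes with MYC, while a shift shared by all genes would stay unseen. With 1 library or population left out the highest G1/S median was -0.84, so no single library or population carries the fall. A slower cycle of the MYC cells at harvest, from the oncogene or from culture density, was not tested. Harvest density is not in the labels, and all MYC libraries could share it.

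On the first principal component the bi libraries lay between B and L, but the keratinocyte differentiation median was 2.02 in bi against B and 1.26 in L against B (0.73 in bi against L, not called, camera adjusted p = 0.217). A physical mixture of B-like and L-like cells would keep shares of L-restricted and B-restricted genes that sum to 1, and the 95% bootstrap interval excluded 1 in 3 of 3 arms, with sums of 0.812 (0.73 to 0.873) in control, 0.665 (0.558 to 0.864) in MYC and 0.468 (0.319 to 0.609) in Her2. These sums do not decide, since the genes were chosen by their level in the same single libraries, which can lower both shares, and the bootstrap covers no variation between libraries. With genes chosen in the other arms the sums were 1.089, 0.998 and 0.527, on 1, 3 and 4 B-restricted genes, too few to decide. A mixture is left open, and no biological explanation was tested.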
